A study of Mus musculus with 6 samples.

How the data were processed

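Gene expression was measured by RNA sequencing of mouse Müllerian duct mesenchyme, the connective tissue around the embryonic duct that forms the female reproductive tract and regresses in males. Cells were sorted for YFP, which marks cells that carry or descend from cells with Amhr2-Cre activity, from embryos at embryonic day 14.5. Per the labels' protocols, 3 male and 3 female libraries were made with the TruSeq v2 kit, each from at least 100 ng of total RNA pooled from 2 to 7 embryos, and sequenced as paired 76-base reads on an Illumina HiSeq instrument. The labels call the replicates biological and give each group replicates 1 to 3.

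The deposited values are raw counts per Ensembl gene for each library, with 5 summary lines that name no gene. TopHat, HTSeq, DESeq and the build mm9 are named in the submitters' processing notes, without versions or roles; the annotation release and the strand setting are not given in the sources used here. The kit does not mark strand, so reads of a gene and an overlapping antisense gene cannot be told apart. Counts of near-identical copies, such as the globin genes, are uncertain for the same kind of reason. Of 37991 gene identifiers, 32919 had a symbol in the reference table. The reference annotation is of the build GRCm38, which differs from mm9, so it was used for names, for X and Y linkage, for transcript GC content and length, and for which genes neighbour each other, and no coordinates are given. The summary lines were left out of library sizes and tests. Counts outside annotated genes made up 3.53% to 18.2% of the uniquely placed counts per library, and counts that fell on more than 1 gene made up 6.51% to 10.0%.

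Everything that follows was computed from the deposited counts, in R 4.3.3. Genes were kept by edgeR's filterByExpr by group, which left 15227, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood test, robust, sex as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 male over female. Their standard errors were derived as the absolute log2 fold change over the square root of the F statistic. CPM values are counts scaled to a common library size with the TMM factors and are given as mean ± SD of 3 libraries per sex. Where a sex held no counts of a gene, a fold is a lower bound against 3 counts over the group; where it held 1 to 3 counts, the ratio has an exact 95% interval that covers counting error only.

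Gene lists for signalling, tissue programmes and other cell types that the sort could hold were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01. The 28 lists with at least 5 tested members formed one adjustment family. Members past the threshold were also counted with p-values adjusted over the list alone. Summed CPM of each list of other cell types was compared by an exact two-sided permutation test, whose smallest p with 3 against 3 libraries is 0.1. The labels were checked by the CPM of Y-linked genes and X-linked genes in each library; the comparison of the Y-linked sum with Xist was chosen after the values were seen.

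The tests, lists, alternatives and the rule for naming genes were fixed before the data were examined, except those said to be chosen later. The named genes were the label check genes, then Sp7, Amh, Amhr2 and Ctnnb1, then the 12 genes with the largest fold change in each direction, and up to 4 members per list with the smallest adjusted p past the threshold, or the member with the smallest p where none passed. The 12 in each direction had to pass the threshold, lie off X and Y, have no overlap between the sexes, reach a mean of 1 CPM in the higher sex and carry a gene symbol. Alternatives were other scalings, other filters, DESeq2 1.42.0, limma-voom, a replicate block, other thresholds and leaving out each library. Corrections for GC content and length, the share of counts outside genes or a surrogate variable (sva 3.50.0), and leaving out both libraries of a replicate number, were added after the data were seen. The GC and length correction fitted splines with 5 degrees of freedom to each library's deviation from the gene mean and used them as an offset; 96.4% of the tested genes had a GC value.

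Libraries held 22511872 to 24749859 counts in genes. The gene test was run on simulated data with 200 changed genes for the male against female comparison, at the spread of the deposited counts. In this and the later simulations each gene was drawn independently, without the deviations that the real libraries shared over genes. The numbers of false calls therefore need not carry over to these data. Over 14949 genes it recovered 0% of the 2-fold, 8% of the 4-fold, 46% of the 8-fold and 74% of the 16-fold changes, with 1 false call among 65. On the same simulated counts DESeq2 recovered 6%, 48%, 96% and 98%, with 50 false calls among 176. The simulations also held a further list of genes shifted for the list test. Calls of those genes are in the totals but count as neither recovered nor false. With a GC and length trend added to simulated counts, the offset recovered 70% of the 4-fold changes over 14946 genes, against 8% without it, with 7 false calls among 140. The added trend was the spline fit of these libraries, of the form that the offset removes, and the spread was that left after it. The gain was thus built in and does not show how the offset handles other bias.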

Results

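The data were gene counts of YFP-sorted Müllerian duct mesenchyme from mouse embryos at embryonic day 14.5, in 3 male and 3 female libraries. In males at this age the duct is exposed to anti-Müllerian hormone (AMH) from the testis, and the series title places osterix, the product of Sp7, downstream of AMH in duct regression. The comparison asked which genes differed between the male and the female mesenchyme. Counts in genes per library were 24749859, 22511872 and 23449923 in female replicates 1 to 3 and 24271103, 22834945 and 24124876 in male replicates 1 to 3.

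Sex-linked genes went with the label in all 6 libraries. Xist, the RNA of the inactive X chromosome, stood at 4729, 277.5 and 1513 CPM in the female libraries and between 1.78 and 2.22 CPM in the male libraries. The summed CPM of 6 Y-linked genes was 395.5, 52.0 and 89.6 in the male libraries and at most 0.441 in a female library. Ddx3y, Kdm5d and Eif2s3y were higher in male and Xist was lower past the threshold, whereas Uty missed it (edgeR adjusted p = 0.066, past it in 10 of 23 alternatives) and Usp9y and Zfy1 held 1 count each. Kdm6a, Kdm5c, Eif2s3x, Ddx3x and Pbdc1, which escape X inactivation, had log2 fold changes between −0.87 and −0.42 and did not pass, although each passed in 2 to 4 of 23 alternatives.

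Male mesenchyme expressed more Sp7 than female mesenchyme. Sp7 (ENSMUSG00000060284), a transcription factor required for bone formation, rose from 29.0 ± 2.47 CPM in female to 228.2 ± 49.4 CPM in male libraries (SD, n = 3 each), a log2 fold change of 2.97 (SE 0.34, edgeR adjusted p = 0.018). Over 24 alternative settings the log2 fold change of Sp7 lay between 2.74 and 3.11, and it passed in 17 of them. The call was lost without female replicate 1, 2 or 3 and without male replicate 2 or 3, and also when replicate 2 or replicate 3 was left out of both sexes. The homeobox genes Msx2 and Dlx5 rose further, from 2.37 ± 0.683 to 209.6 ± 50.7 CPM and from 0.475 ± 0.174 to 60.8 ± 21.0 CPM. Wif1, a secreted WNT inhibitor, rose from 0.335 ± 0.110 to 88.8 ± 14.98 CPM, and Nkd2, a feedback inhibitor of WNT signalling, fell from 316.7 ± 74.7 to 36.6 ± 5.63 CPM. Amhr2, the AMH receptor gene whose locus drives the Cre, stood at 530.3 ± 233.7 CPM in female and 338.8 ± 158.4 CPM in male libraries and did not pass, with a log2 fold change of −0.65 (SE 0.53). In 5 of 24 alternatives Amhr2 was lower in male past the threshold, among them the GC and length offset (−0.97, SE 0.18, adjusted p = 0.0256) and a replicate block (adjusted p = 0.00074). Its log2 fold change lay between −0.97 and −0.24 over the 24. Ctnnb1, which encodes beta-catenin, had a log2 fold change of −0.13 (SE 0.33) and did not pass either, in this fit or in any of 24 alternatives.

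**Figure D1:**
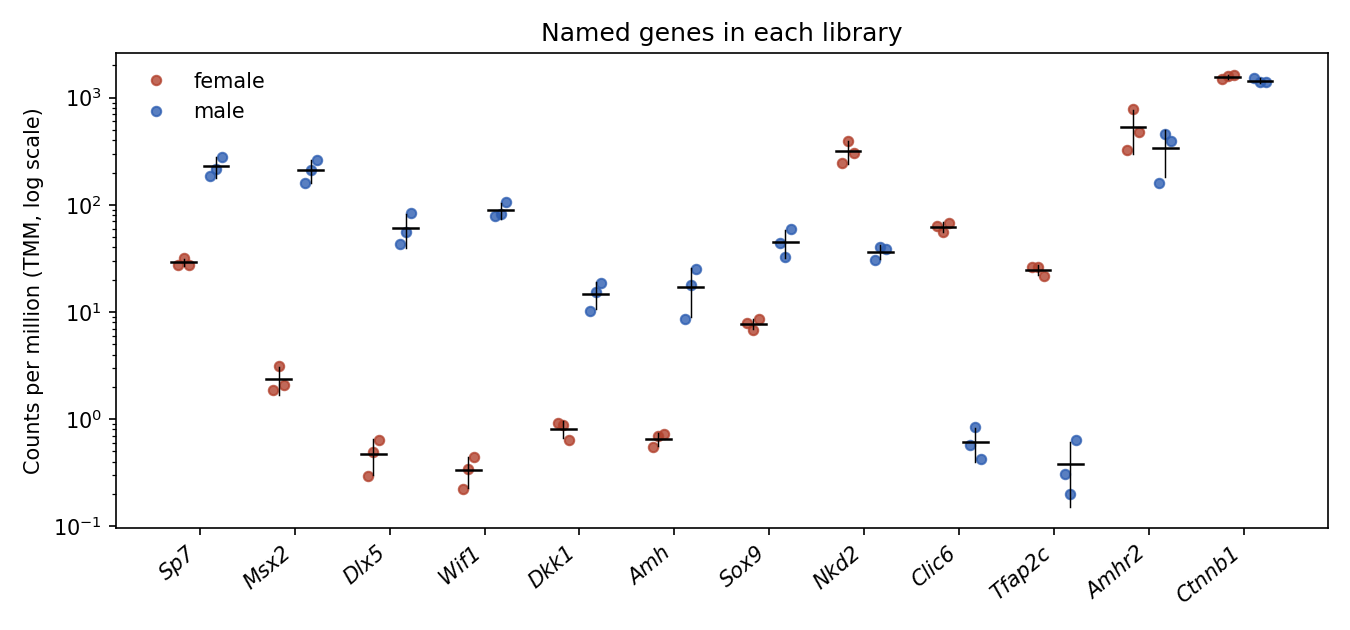
Expression of 12 named genes in each of the 6 libraries, in CPM on a log axis, with points for libraries, horizontal bars for the mean of 3 libraries per sex and vertical bars for the SD. Sp7 lies between 184.9 and 282.0 CPM in the male libraries and between 27.5 and 31.9 CPM in the female libraries, whereas the sexes overlap for Amhr2 and Ctnnb1.

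Of 15227 genes tested, 128 were higher and 59 lower in male (edgeR, adjusted p threshold 0.05). In all 187 of these genes the male and female libraries did not overlap, which held for 13.7% of the genes tested, against 10% by chance with 3 libraries per sex. The smallest absolute log2 fold change among them was 1.93. Among the genes with the largest rise, Ankrd63, Syt1, Dlx6, Dlx2 and Prr9 had log2 fold changes of 8.67, 7.29, 7.22, 6.70 and 6.63. These rest on 4, 23, 6, 4 and 6 counts over the 3 female libraries, so most of the sizes are uncertain. Female libraries held 1 count or none of several others. Ibsp, a bone matrix sialoprotein gene, had 472 male counts and a ratio of 488.5 (95% interval 87.2 to 19333). Hand1 had a ratio of 237.0 (42.1 to 9401), and Nmu was at least 26.9-fold higher in male. Dlx6os1 had 581 male counts against 1, but it overlaps the Dlx6 region on the opposite strand and reads of the pair cannot be told apart. Among genes that fell, Clic6 went from 62.4 ± 6.60 to 0.612 ± 0.212 CPM, the transcription factor gene Tfap2c from 24.7 ± 2.78 to 0.379 ± 0.226 CPM and the axon guidance gene Slit1 from 11.2 ± 4.48 to 0.420 ± 0.101 CPM. Cpxm2, Spock1, Gpr83, Marveld3, Shisa6 and Lypd6b fell with log2 fold changes from −5.31 to −3.55. Spock1 and Gpr83 rest on 5 and 4 male counts in all, so their sizes are uncertain too. Lgi1 and Drd1 were 102.0 times (27.9 to 847.3) and 36.1 times (12.03 to 177.6) higher in female by count ratio. The counts of called genes depended on single libraries: leaving out female replicate 1, 2 or 3 left 14, 5 and 0 genes, and leaving out male replicate 2 or 3 left 7 and 0. In the settings with 0 calls by edgeR, 884 of 15866 and 938 of 15867 tested genes had an unadjusted p under 0.05. In the main fit 1398 of 15227 did. A share of 0.05 would do so by chance if no gene differed and the p-values were even. Deviations that libraries share over genes can push that share either way, so it does not show whether the sexes differed. Without male replicate 1, 141 were higher and 32 lower. The libraries also differed within each sex along transcript GC content, and with a GC content and length offset, chosen after the data were seen, 460 genes were higher and 445 lower in male, 182 of the 187 among them, so that higher genes made up 50.8% of the calls in place of 68.4%.

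**Figure D2:**
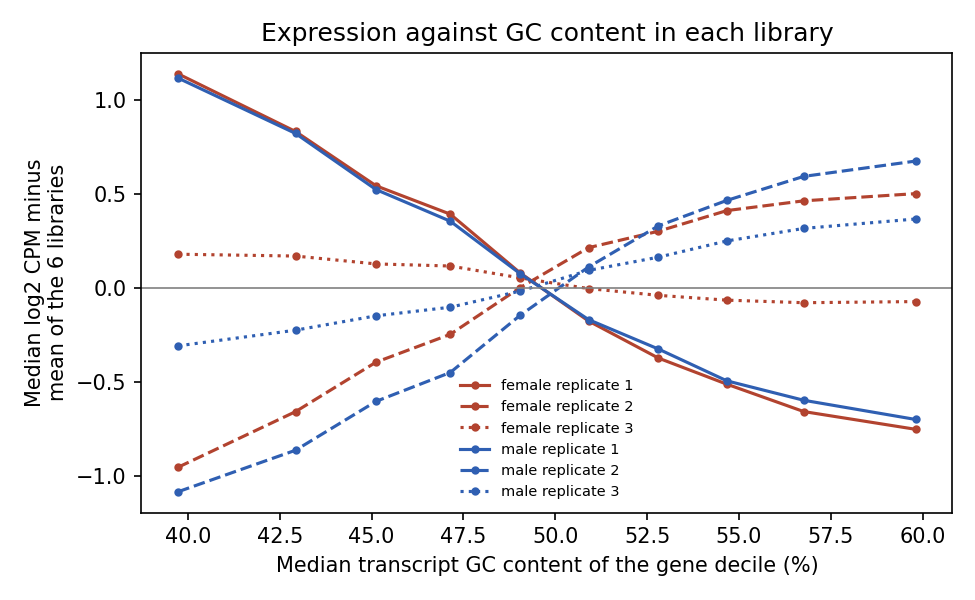
Median log2 CPM of each library relative to the mean of the 6 libraries, over 10 groups of tested genes ordered by transcript GC content in percent, with 1 line per library. In the group of lowest GC content both replicate 1 libraries lie above 1.11 and both replicate 2 libraries lie below −0.95, in either sex.

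Genes commonly induced by BMP-SMAD signalling, the pathway AMH shares with bone morphogenetic proteins, were higher in male as a list (camera adjusted p = 3.76e-15; adjusted p = 0.126 with an estimated correlation). Of 13 tested members, 4 rose, none fell and 9 did not pass over all genes, and 10 rose when adjusted over the list alone. Msx2, Id4, Hey1 and Bmper rose, the last 3 with log2 fold changes of 2.86, 2.61 and 2.49. Smad6 and Nog, feedback inhibitors of the pathway, had log2 fold changes of 3.51 (SE 0.60) and 2.55 (SE 0.44) and missed the threshold over all genes, and Id1 had −0.31 (SE 0.68). The 11 AMH and BMP receptor and SMAD genes did not pass as a list (camera adjusted p = 0.740); Smad9 alone of them rose, from 2.74 ± 1.05 to 38.3 ± 16.1 CPM, and 2 rose when adjusted over the list alone.

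The osteoblast list was higher in male (camera adjusted p = 2.49e-09; adjusted p = 0.126 with an estimated correlation). Of 12 tested members 5 rose, the same number when adjusted over the list alone, and none fell. These were Sp7, Ibsp and the homeobox genes Dlx3, Dlx5 and Dlx6, most of them regulators of transcription. Runx2, Alpl, Col1a1 and Sparc, further genes of bone-forming cells, had log2 fold changes of 0.62, 0.32, 0.40 and 0.37 and did not pass. In the chondrocyte list 1 of 9 tested members rose, Sox9, with a log2 fold change of 2.55 (SE 0.37), and 2 when adjusted over the list alone (camera adjusted p = 0.011; adjusted p = 0.132 with an estimated correlation); the cartilage collagen gene Col2a1 had −0.46. The chondrocyte list did not pass without female replicate 2 (adjusted p = 0.087) or with no expression filter (adjusted p = 0.0855).

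Secreted WNT antagonists moved in both directions. Wif1, Dkk1 and Draxin rose and Frzb fell among 11 tested members, and 4 rose and 2 fell when adjusted over the list alone; Dkk1 went from 0.815 to 14.7 CPM and Frzb from 15.9 to 3.91 CPM. The list missed the threshold (camera adjusted p = 0.056; adjusted p = 0.486 with an estimated correlation) and passed, higher in male, in 6 of 23 alternatives. These were no expression filter (adjusted p = 0.0177), fry (0.0080), leaving out female replicate 1 or 3 or male replicate 2 (0.0399, 0.0279 and 0.0177), and leaving out both libraries of replicate 2 (0.0220). Among 15 WNT-beta-catenin response genes Dkk1 and Cd44 rose and Nkd2 fell, 2 rose and 2 fell when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.587). Axin2, a common readout of the pathway, had a log2 fold change of −1.08 (SE 0.28) and did not pass over all genes. Adjusted over the list alone, Axin2 was 1 of the 2 that fell (edgeR adjusted p = 0.0256).

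Cell cycle genes were lower in male as a list (camera adjusted p = 1.09e-05; adjusted p = 0.132 with an estimated correlation). No single member passed, over all genes or adjusted over the list alone, but all 18 had negative log2 fold changes, with a median of −0.70. Rrm2, the member with the smallest p, passed in 5 of 24 alternatives, among them the GC and length offset (edgeR adjusted p = 0.0152). Smooth muscle genes were higher as a list (camera adjusted p = 0.00022; adjusted p = 0.126 with an estimated correlation). None of 9 passed over all genes, while 5 rose and 2 fell when adjusted over the list alone; Actg2, Cnn1 and Myocd had log2 fold changes of 4.24, 3.57 and 3.45, with Cnn1 past the threshold in 14 of 24 alternatives, and Myh11, a smooth muscle myosin gene, had −2.39. Matrix proteases and their inhibitors were higher as a list (camera adjusted p = 0.0012; adjusted p = 0.126 with an estimated correlation), with Mmp19 the 1 of 17 tested members that rose and 2 when adjusted over the list alone.

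**Figure D3:**
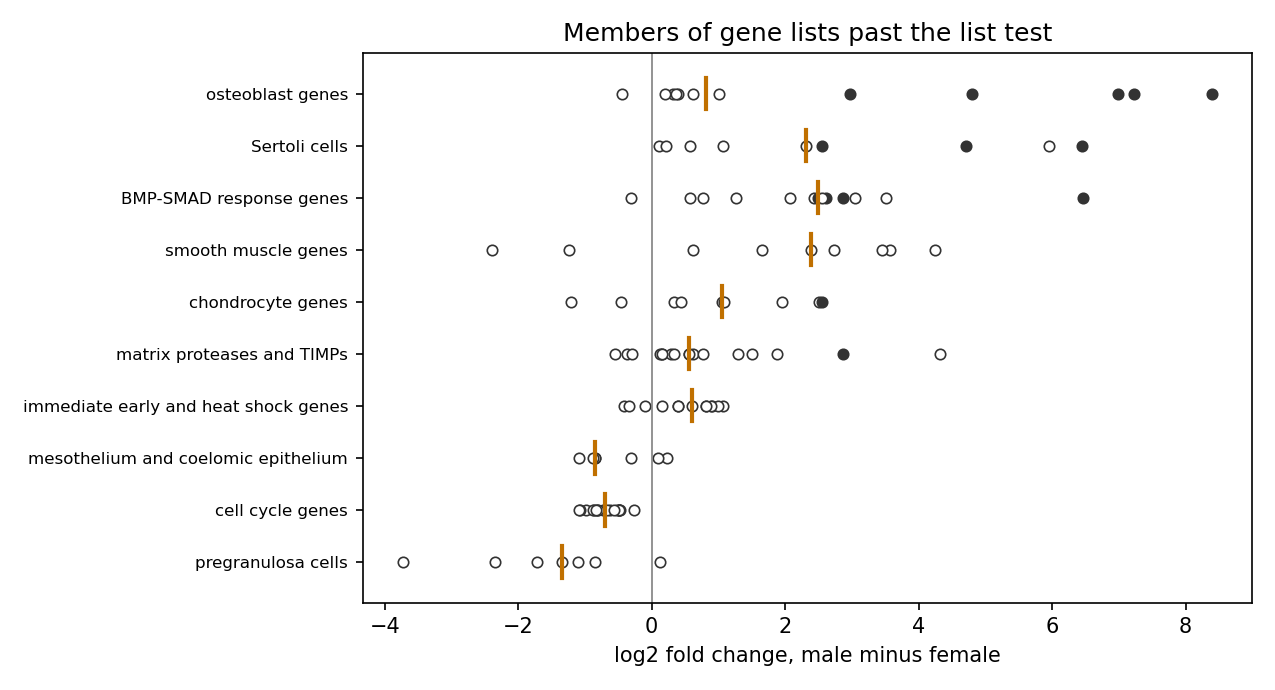
Log2 fold change, male minus female, of each tested member of the 10 gene lists past the camera threshold, with filled points for members past the gene threshold, open points for the others and vertical bars for the list median. All 18 cell cycle genes lie below 0; fitted values of Ibsp and Cst9 rest on 1 and 2 female counts.

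Markers of other cell types differed between the sexes too. Sertoli cell genes, typical of the fetal testis, were higher in male (camera adjusted p = 2.49e-09; adjusted p = 0.126 with an estimated correlation), with 3 of 9 members risen and 5 when adjusted over the list alone. Amh rose from 0.653 ± 0.0898 to 17.2 ± 8.24 CPM and Sox9 from 7.74 to 45.2 CPM, and Cst9 had a count ratio of 106.6 (29.1 to 886.0). The summed CPM of the Sertoli list was 26.7 ± 5.51 in female and 112.9 ± 27.6 in male libraries (exact permutation p = 0.1, the smallest possible; adjusted p = 0.217). The same p was found for the mesothelium sum, at 743.8 ± 69.0 CPM in female and 567.3 ± 9.93 CPM in male libraries, for the neuron sum, at 23.8 ± 6.95 and 72.3 ± 5.24 CPM, most of it Stmn2 in male, and for the kidney sum, at 175.5 ± 39.5 and 84.9 ± 21.6 CPM, most of it Sall1. It was also found for the pregranulosa sum, at 111.5 ± 20.9 CPM in female and 40.5 ± 16.003 CPM in male libraries, and for the endothelium sum, at 90.8 ± 15.9 and 235.6 ± 87.8 CPM, of which Kdr, at 66.2 and 207.6 CPM, made up the most. Pregranulosa cell genes, typical of the fetal ovary, were lower in male (camera adjusted p = 0.00022, and 0.132 with an estimated correlation). None of 7 passed over all genes and 3 fell when adjusted over the list alone. Irx3, the member with the smallest p, had a log2 fold change of −3.73 (edgeR adjusted p = 0.058). It passed in 9 of 24 alternatives, among them the GC and length offset (adjusted p = 0.0145). Mesothelium genes were lower (camera adjusted p = 0.020; adjusted p = 0.150 with an estimated correlation) and immediate early and heat shock genes, which respond to cell dissociation, were higher (camera adjusted p = 0.032; adjusted p = 0.717 with an estimated correlation), with no member past the gene threshold in either, overall or adjusted over the list alone. The mesothelium call was lost without female replicate 2 or 3 or male replicate 1 (adjusted p = 0.168, 0.051 and 0.193), and without both libraries of replicate 3 (0.088). The immediate early call was lost without female replicate 1 or 3 or male replicate 2 (0.470, 0.141 and 0.376) or with the GC and length offset (0.074). It was also lost with that offset and a replicate block (0.0752), with 1 surrogate variable (0.0918) and without both libraries of replicate 1 or 3 (0.183 and 0.101). By fry, which does not compare a list with other genes, the pregranulosa, mesothelium and immediate early calls were lost (adjusted p = 0.054, 0.122 and 0.627).

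The other lists did not pass the camera test. Their adjusted p-values were 0.104 for autophagy and lysosome genes, 0.256 for collagens and matrix proteins, 0.587 for pro-apoptotic and for hedgehog response genes, 0.740 for posterior HOX and for androgen response genes, 0.786 for female tract mesenchyme genes and 0.825 for retinoic acid pathway genes. For other cell types they were 0.219 for neurons and Schwann cells, 0.383 for erythroid cells, 0.460 for endothelium, 0.587 for fetal Leydig cells and for macrophages and leukocytes, 0.740 for duct epithelium and 0.914 for kidney progenitors and stroma. The autophagy and lysosome list passed, higher in male, in 7 of 23 alternatives. These were a replicate block without or with the GC and length offset (adjusted p = 0.0117 and 0.00788), the share of counts outside genes as a covariate (0.0102), 1 surrogate variable (0.0131), leaving out female replicate 2 or male replicate 1 (0.0222 and 0.0245), and leaving out both libraries of replicate 2 (0.0393). With an estimated correlation it had 0.717. The duct epithelium list passed, lower in male, without female replicate 1 (0.0260). In the androgen response, hedgehog response, fetal Leydig, neuron and kidney lists the median, the mean and the camera direction differed in sign. Single members did change: Col14a1, Stmn2, Gdnf and Gata3 rose, with log2 fold changes of 1.95, 2.50, 2.82 and 2.81, and Epcam, an epithelial adhesion gene, fell from 13.7 to 2.58 CPM. With the GC and length offset Stmn2 did not pass, at a log2 fold change of 2.70 (SE 0.62) against 2.50 (SE 0.33). Adjusted over the list alone, 2 genes rose among collagens and matrix proteins and 1 each among pro-apoptotic, female tract mesenchyme, fetal Leydig and neuron genes. By the same adjustment 1 rose and 2 fell among duct epithelium and among kidney genes, and none passed in the other tested lists of this paragraph. Germ cell and skeletal muscle lists had 3 tested members each, too few for the list test, and no member of either passed over all genes, with 1 skeletal muscle gene risen when adjusted over the list alone.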

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

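Of the tests in this part, those on GC content and length and those on the number of called genes were chosen after the results were seen, and the others before. Counts outside annotated genes went into no test of the report except as a covariate in 1 alternative. They are given as a signal outside the genes. With no control library the only reference is a count of 0, which any share of this size passes, so nothing follows from passing it. Their share was 17.5%, 3.53% and 8.65% in female replicates 1 to 3 and 18.2%, 5.45% and 5.50% in male replicates 1 to 3.

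Replicate 1 and replicate 2 libraries differed within each sex, along the first principal component, which held 65.6% of the variance. GC content and transcript length accounted for 0.574 of the variance between genes of the replicate 1 minus replicate 2 difference, so a bias of the libraries by GC content and length may be part of it. The fitted trend is not the whole: after it was removed, the deviations of female and male replicate 1 still correlated over genes at 0.845 (genes are not independent replicates). The fit used the longest reference transcript of each gene. Bias by GC content or length that it misses may remain, so such bias as the whole stays open. Cells of other types in the replicate 1 or replicate 2 sorts stay open: 1 of 11 lists of other cell types, the duct epithelium, lay outside the range of random lists matched on expression. That range was the central 95% for each list, without adjustment over the 11 lists, so 1 outside can arise by chance. The test used values with the GC and length trend removed. Without that correction, the summed CPM of the duct epithelium list was 209.1 and 747.9 in female and 164.8 and 509.7 in male replicates 1 and 2. These sums may hold part of the GC trend. The bound set beforehand, at most 1 list outside, cannot exclude a single admixed cell type, which needs no more than 1 list. Genomic DNA in the replicate 1 libraries stays open too: olfactory receptor genes took at least 2.84 times the share of counts there that they took in any other library, and the design names no biological difference between replicates, so none was tested.

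Amh was higher in the male libraries, in 3 of 3. Reads from the neighbouring gene Sf3a2 are argued against, because Sf3a2 had a log2 fold change of 0.10 (SE 0.55). Sertoli cells in the male sorts stay open as a candidate source: the other 8 Sertoli genes had a median log2 fold change of 1.69 and 2 of them passed, although Ptgds, Mro and Fgf9 had 0.21, 0.57 and 0.11, and Sox9 also stands in the chondrocyte list. The sort on YFP does not exclude gonadal cells with Amhr2-Cre activity, and the sex of the embryos, the biological difference the design names, stays open and untested as a cause within the mesenchyme itself.

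The number of genes past the threshold between the sexes was 187. Among the 10 splits of the 6 libraries into 3 and 3, 2 gave as many, the real one included, and the highest other gave 7262; so few splits cannot give a share under 0.05. That split set female replicates 1 and 3 and male replicate 1 against the rest, which points to a structure of the samples other than sex, and without both replicate 1 libraries 225 genes were higher and 129 lower in male. GC content and length bias may widen the spread between replicates: with that trend as an offset, 905 genes passed and the common dispersion went from 0.265 to 0.121.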

How the results depend on the processing

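GC and length, no-feature, surrogate variable and both-replicate settings were chosen after the data were seen. For the 128 genes higher and 59 lower in male, other scalings, filters, limma-voom, robust estimation off, a 2-fold minimum and leaving out sex-linked or the 20 most abundant genes gave counts within 1.5 times. DESeq2 gave 409 and 312. In simulated counts, which lacked deviations shared over genes, DESeq2 came with more false calls. An adjusted p threshold of 0.01 left 3 and 1. The GC and length offset gave 460 and 445, the share of counts outside genes as a covariate 1404 and 1422, and 1 surrogate variable 1766 and 1883. Leaving out single libraries gave 0 to 141 higher and 0 to 32 lower, from fewer samples. Leaving out both libraries of replicate 1, 2 or 3 gave 225, 0 and 0 higher and 129, 0 and 0 lower. Where none passed, 1103 of 15757 and 455 of 15687 tested genes had an unadjusted p under 0.05 in edgeR. A share of 0.05 would do so by chance if no gene differed and the p-values were even. Deviations shared over genes, left in the spread of these fits, can push it either way, so these shares cannot decide whether the sexes differed. The labels do not say that replicate numbers pair the samples, and not every number clearly did so in the values. Deviations of libraries numbered 1, 2 and 3 correlated between the sexes at 0.93, 0.85 and −0.07, and male replicate 3 correlated best with female replicate 2 (0.59). By log2 CPM itself female replicate 3 correlated best with male replicate 3 (0.935), but male replicate 3 with female replicate 2 (0.945). With the number as a replicate block 1997 were higher and 2167 lower, and with the GC and length offset as well 2069 and 2349. Of 10 lists called, 7 higher and 3 lower, an estimated correlation left 0 and 0 (smallest adjusted p = 0.126, while fry, which does not compare a list with other genes, called 8), and fry left 1 lower. The cause of these changes was not tested. No called gene changed direction in the settings run. For named genes, calls were unchanged in 1298 comparisons with an alternative, lost in 342, most with libraries left out, and gained in 123; for lists these were 601, 27 and 14. In each of 13 other cell type lists, library size only moved the male minus female difference of log2 sums by under 1 within-sex SD. The label check gave 6 of 6 libraries with 4 Y-linked genes as with 6. At the spread of these counts, edgeR recovered 0% of simulated 2-fold changes.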

Other observations

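The genes in this paragraph were chosen after their values were seen. In male mesenchyme the collagen genes Col15a1 and Col13a1 rose from 6.54 ± 0.346 to 148.5 ± 20.02 CPM and from 13.4 ± 4.26 to 272.6 ± 85.1 CPM (SD, n = 3 each). Gata5, a transcription factor gene, rose from 2.04 ± 0.658 to 169.2 ± 63.0 CPM, Gdf10, a TGF-beta family ligand gene, from 22.1 ± 6.03 to 195.3 ± 51.0 CPM, and Fgfr3 from 3.46 ± 0.551 to 53.0 ± 9.08 CPM. Brinp1 (2.99 to 45.5 CPM), Ntrk3 (2.22 to 27.1 CPM) and Cadps (0.5002 to 19.5 CPM) rose as well. In the other direction, Bmp7, a BMP ligand gene, fell from 120.3 ± 15.96 to 16.99 ± 4.85 CPM in male. Col7a1 fell from 117.8 ± 5.82 to 14.6 ± 1.32 CPM, Lmx1a from 33.4 ± 3.84 to 5.15 ± 1.40 CPM and Tril from 373.4 ± 27.9 to 57.5 ± 6.98 CPM. All of these passed the edgeR threshold, with no overlap between the sexes.

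Some genes higher in male that neighbour each other were noticed in the results, and the test of this was chosen afterwards. The hypothesis was that called genes lie next to each other along chromosomes more often than random genes. Among 122 genes higher in male with a position, 6 adjacent, non-overlapping pairs of tested genes were both called, against a mean of 0.854 and a maximum of 6 in 10000 random draws of as many tested genes (permutation p = 0.00030, adjusted over both directions 0.00060). Among the pairs were Ankrd63 with Plcb2, Stmn2 with Hey1, Bend4 with Shisa3, Dlx6 with Dlx5 and Me1 with Prss35. Among 57 genes lower in male there was 1 pair, Tfap2c with Bmp7 (permutation p = 0.175). The pairs themselves prompted the test, the draws were not matched on expression, and some pairs are related copies, as Dlx5 and Dlx6 are. No cause was tested.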
